A study of Mus musculus with 24 samples.

How the data were processed

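RNA of 24 mouse samples was extracted with TRIzol, labelled with biotin and measured on single-colour Affymetrix gene arrays, per the labels. The deposited values are log2 intensities of 241576 probe sets, which the authors made with the robust multi-array average method (RMA) in oligo 1.14 under R 2.15, per the submitters' processing notes. RMA corrects the background, quantile normalizes across arrays and summarises probes, so that the deposited values show relative and not absolute changes. The probe masking, the annotation the authors used, scan dates and the genome build are not given in the sources used here, and no coordinates are printed for that reason. Every column of the table matched a sample, so 0 columns were left out.

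Gene symbols came from the platform's annotation of the probe sets. Among the probe sets, 213361 had 1 symbol, 5107 had several and 23108 had none, and the latter 2 kinds were left unnamed. Symbols date from the annotation, and the current ones were taken through the synonyms of the RefSeq table of GRCm38.p6. The probe sets of a gene, median 8, were combined by median polish into 20893 genes, of which 2655 rested on 1 probe set. A gene was kept where at least 3 arrays lay above the table's median of 7.61 (log2), which left 10988 genes. The number of genes above that value ranged from 7899 to 9363 per array, the arrays give no counts of molecules, and their number limits the precision.

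Samples were grouped by the titles and genotypes in the labels. Each comparison was a contrast of a linear model over all 24 arrays with 4 groups, fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3 (version 1.17.8 of data.table read the values), with Benjamini-Hochberg adjustment over the genes of that comparison at 0.05. The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names Gnas and, among called genes, the 10 largest rises and falls against adult cerebellum and the 5 largest against developing cerebellum, where arrays of the groups did not overlap. Between the tumour groups it names the 10 largest in each direction with overlap allowed. Unnamed gene models, microRNAs, olfactory and vomeronasal receptors and immunoglobulin segments were left out. Members of lists are named as examples, those with the largest changes and those that did not pass or moved the other way.

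The 39 gene lists, written from general knowledge of the tissue, held 455 entries, and some genes are in several lists. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. In all 5 comparisons no call of camera held with an estimated correlation. The list of imprinted transcripts near Gnas held no tested gene and was not analysed here. Correlations between arrays were computed across the genes kept.

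The model was tested on simulated data with 200 changed genes among the 10988. The noise was drawn independently for each gene, with the same spread in all groups. The real groups differed in spread, so the rates below may not hold for them. Between 7 and 13 unchanged genes were called per comparison. Of changes of log2 1 it recovered 85% for hGFAP tumours against adult cerebellum, 84% for Oligo1 tumours against adult cerebellum, 84% between tumour groups, and 68% and 80% for hGFAP and Oligo1 tumours against developing cerebellum. No array was a copy of another: the closest arrays, hGFAP tumours 1 and 2, correlated at 0.990. Whether any arrays share a tumour or mouse cannot be told from this.

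The alternatives were other summaries of probe sets, no filter and a stricter filter (8.99), quantile normalization again, centring of arrays, eBayes with trend and robust settings, a fit of only the groups compared, array weights, leaving out each array, strain as a covariate, adult arrays of the mixed strain only, each naming style of tumours, blocks of naming style and replicate number, developing arrays without embryonic day 15, and a 2-fold minimum. After seeing the data, sex as a covariate, a granule neuron marker covariate, and fits without hGFAP tumour 5 or without hGFAP tumour 5 and Oligo1 tumour 6 were added, as were fits of only the tumour groups with each block, naming style or the granule covariate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.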

Results

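Gene expression was measured in mouse cerebellum and cerebellar tumours on 24 single-colour Affymetrix gene arrays, 1 array per sample. There were 8 tumours of hGFAP:GnasCKO mice and 8 tumours of Oligo1:GnasCKO mice, named hGFAP and Oligo1 tumours here, all dissected at endpoint and recorded as biological replicates. Gnas encodes Gsα, the stimulatory G protein subunit that activates adenylyl cyclase, and the series title presents it as a tumour suppressor in medulloblastoma driven by Sonic Hedgehog (SHH), a mitogen of cerebellar granule neuron precursors. The normal cerebella were 5 adult samples and 3 developing ones, of embryonic days 15 and 18 and postnatal day 0, with 1 array per age. Tumours and 3 adult samples (postnatal day 60, postnatal day 60 and recorded only as adult) were of mixed strain. The other 2 adult samples (postnatal days 95 and 122) and all developing ones were C57BL/6. After dim genes were left out, 10988 of 20893 genes were tested. The number of genes brighter than the median of the whole table ranged from 7899 (hGFAP tumour 5) to 9363 per array, and the number of arrays limits the precision.

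Gnas was lower in both tumour groups than in adult cerebellum. Its log2 level was 8.16 ± 0.73 (SD, n = 8) in hGFAP tumours and 7.82 ± 0.54 (n = 8) in Oligo1 tumours, against 9.69 to 9.87 in the 5 adult arrays. The difference from adult was -1.64 (SE 0.29, 3.11-fold lower, limma adjusted p = 0.00011) in hGFAP and -1.97 (SE 0.29, 3.92-fold lower, adjusted p = 4.5e-06) in Oligo1 tumours. All 16 tumours lay below the lowest adult array, the nearest being hGFAP tumour 5 at 9.33 and hGFAP tumour 6 at 9.16. Against developing cerebellum Gnas was lower by a log2 difference of -1.77 (adjusted p = 0.0005) in hGFAP and -2.10 (adjusted p = 5.21e-05) in Oligo1 tumours, and the hGFAP call ended with strain as a covariate (-1.79, adjusted p = 0.0763). The tumour groups differed by 0.34, which did not pass the test (adjusted p = 0.324). Of the 31 Gnas probe sets, 23 were bright in adult cerebellum, of which limma called 21 lower in hGFAP and 22 in Oligo1 tumours, with median differences of -1.89 and -2.15. The labels do not name the deleted part of the gene, and a probe set outside it checks nothing.

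**Figure D1:**
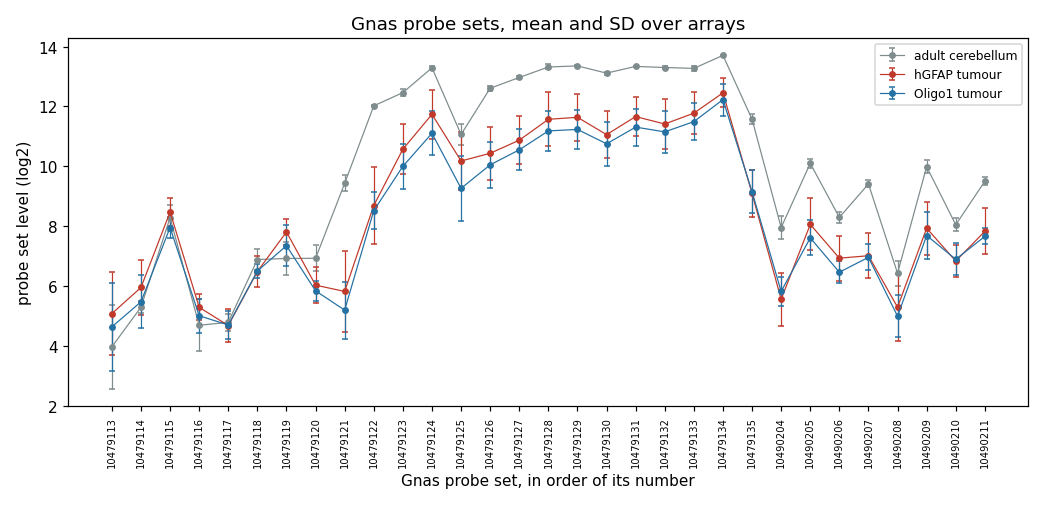
Mean log2 level (vertical axis) of each of the 31 Gnas probe sets (horizontal axis) in adult cerebellum (n = 5), hGFAP tumours (n = 8) and Oligo1 tumours (n = 8), with bars of 1 SD. Of the 23 probe sets that were bright in adult cerebellum, the mean of 22 was lower in hGFAP and of 23 in Oligo1 tumours.

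The comparison of hGFAP tumours with adult cerebellum asked what distinguishes these tumours from the mature tissue. Lcn2, an iron-binding acute phase protein, rose without overlap between the groups (log2 difference 6.37, SE 0.41, at least 82.8-fold, adjusted p = 1.65e-09). Atoh1, the transcription factor that marks granule neuron precursors, rose at least 57.1-fold (log2 5.83, SE 0.60, adjusted p = 3.93e-07), from 4.98 ± 0.27 (SD, n = 5) to 10.82 ± 1.76 (n = 8). The neuronal transcription factors Insm1 (5.77) and Nhlh1 (5.69) rose with it, as did the cell cycle genes Mki67 (5.38), Cdk6 (5.10), Top2a (5.00) and Ccna2 (4.96). Hsd11b2, which inactivates glucocorticoids, rose by 5.25 and Gpnmb, a glycoprotein of activated macrophages, by 5.07. In the adult arrays these 10 genes lay below the filter value of 7.61, at most at 6.53 (Gpnmb), where values near background can shrink a difference. The differences are lower bounds only in this sense and have no order. The words at least and lower bound, here and below, have this sense alone. They do not cover sampling error, which the SE gives. The filter value is the table's median and not a measured detection limit. The largest falls without overlap included Dao, which oxidises D-amino acids (-3.35), the carbonic anhydrase gene Car7 (-3.02), Gsbs, the Purkinje cell G-substrate now named Ppp1r17 (-2.95), and Eomes, a transcription factor of unipolar brush cells (-2.94, a lower bound in size, as every hGFAP array lay below the filter value). The glutamate receptor gene Grm4 (-2.91), the vesicular glutamate transporter gene Slc17a7 (-2.64) and the corticotropin-releasing hormone receptor gene Crhr1 (-2.57) also fell, as did Plch2 (-2.64), Atp2a3 (-2.59) and Tmem90b, now Syndig1 (-2.55).

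**Figure D2:**
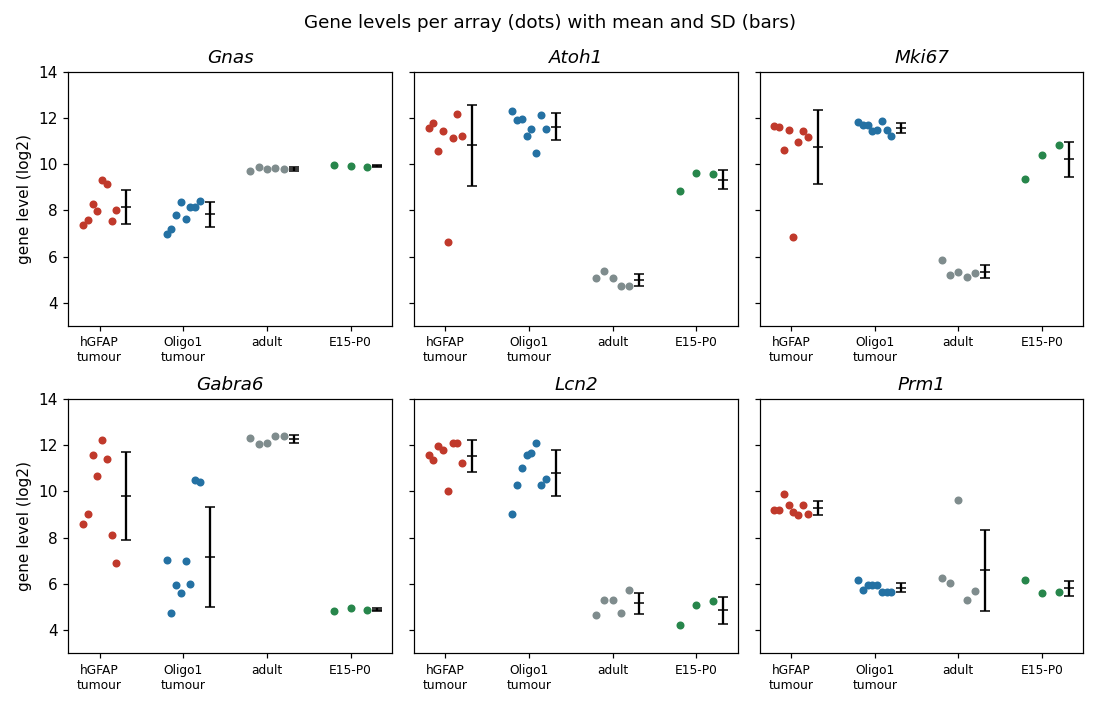
Log2 level (vertical axis) of Gnas, Atoh1, Mki67, Gabra6, Lcn2 and Prm1 in each array (points) of the 4 groups (horizontal axis), with the group mean and bars of 1 SD. Atoh1 averaged 4.98 in adult cerebellum, 10.82 in hGFAP and 11.63 in Oligo1 tumours, and hGFAP tumour 5 lay apart from the other hGFAP tumours at 6.62.

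Of the 13 tested genes of the SHH pathway and its targets, 11 rose in hGFAP tumours, 0 fell and 2 did not pass, with the same 11 adjusted over the list alone. Sfrp1 (4.32), the cyclin gene Ccnd2 (4.06) and Mycn (3.52) led after Atoh1. The effector gene Gli1 rose by 1.93 and the receptor gene Ptch1 by 0.85, while Gli3 (-0.75) and Boc (0.25) did not pass. The SHH median was 1.93 (camera adjusted p = 6.12e-07, and adjusted p = 0.342 with an estimated correlation). All 19 G2 and M phase genes rose, with a median of 3.86 (camera adjusted p = 4.8e-15), as did all 18 S phase genes (median 2.26, adjusted p = 1.23e-10). All 11 DNA repair genes (median 1.96, camera adjusted p = 5.99e-07) and all 11 MYC and ribosome biogenesis genes (median 1.03, adjusted p = 9.22e-06) rose as well. These counts were the same adjusted over each list alone, and each of these 4 calls ended at adjusted p = 0.342 with an estimated correlation. Of 15 granule neuron precursor markers 8 rose, 0 fell and 7 did not pass (8 rose adjusted over the list alone). Dcx rose by 3.89 and Barhl1 by 3.09, while Zic1 (-0.15) and Pax6 (0.04) did not pass. The precursor list had a median of 0.88 (camera adjusted p = 0.00107, and adjusted p = 0.342 with an estimated correlation). Of 5 SHH medulloblastoma markers Atoh1, Sfrp1 and Hhip rose, which the SHH pathway list also holds, and 0 fell (3 adjusted over the list alone). Their camera adjusted p was 0.0227 (adjusted p = 0.342 with an estimated correlation). In the other comparisons with normal tissue this list did not pass: 4 rose and 1 fell in Oligo1 tumours against adult (0.0926), and 2 and 3 rose and 1 fell in hGFAP (0.622) and Oligo1 tumours (0.663) against developing cerebellum. In hGFAP tumour 5 Atoh1 stood at 6.62 and Mki67 at 6.87, against at least 10.59 and 10.63 in the other 7 hGFAP tumours.

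All 10 mature granule neuron markers fell in hGFAP tumours (10 adjusted over the list alone), among them Grm4, Slc17a7 and the GABA receptor subunit genes Gabra6 (-2.44) and Gabrd (-2.42). The granule neuron median was -2.26 (camera adjusted p = 0.00394, and adjusted p = 0.397 with an estimated correlation). Of 12 Purkinje cell markers 10 fell (11 adjusted over the list alone), Pcp4 did not pass (-0.53) and Foxp2, a transcription factor also found outside Purkinje cells, rose by 1.49. Rgs8 (-2.45), the glutamate transporter gene Slc1a6 (-2.44) and the parvalbumin gene Pvalb (-2.42) fell most after Gsbs. The Purkinje median was -2.11 (camera adjusted p = 0.00972, and adjusted p = 0.397 with an estimated correlation). Of 8 markers of inhibitory interneurons and unipolar brush cells 7 fell (7 adjusted over the list alone), with Tcfap2b at -2.47 and the glutamate decarboxylase gene Gad2 at -2.39, and Lmx1a did not pass (-0.33). Their median was -2.12 (camera adjusted p = 0.00282, and adjusted p = 0.342 with an estimated correlation). Of 13 synapse and general neuron genes 10 fell and 3 did not pass (10 adjusted over the list alone), with Syt1 at -2.29 and Camk2a at -1.90. The synapse median was -1.36 (camera adjusted p = 0.00521, and adjusted p = 0.397 with an estimated correlation).

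Of 24 genes of Gs, cyclic AMP and protein kinase A signalling 13 fell, 3 rose and 8 did not pass, with the same counts adjusted over the list alone, and 15 fell and 5 rose without hGFAP tumour 5. Gnal, which encodes the related G protein subunit Gαolf, fell (-2.16), as did the adenylyl cyclase gene Adcy1 (-1.95) and the phosphodiesterase gene Pde10a (-1.80). The protein kinase A regulatory subunit gene Prkar2b rose by 1.17, Gpr161 by 0.72 and Adcy6 by 0.32. The Gs median was -0.44 (camera adjusted p = 0.0471, and adjusted p = 0.342 with an estimated correlation), and the list holds Gnas itself. After a further quantile normalization its adjusted p was 0.0669. Of 8 CREB and immediate early targets 6 fell, 0 rose and 2 did not pass (8 fell adjusted over the list alone), with Nr4a3 at -1.99, Nr4a1 at -1.40 and Arc at -1.39. The CREB median was -0.95 (camera adjusted p = 0.00282, and adjusted p = 0.342 with an estimated correlation). Neuron marker lists also fell in this comparison. Whether the changes of Gs and CREB genes are separate from those of neuron markers was not tested, here or below.

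All 12 microglia and macrophage markers rose in hGFAP tumours (12 adjusted over the list alone), led by the complement gene C1qc (2.86), Cd68 (2.51) and C1qb (2.37). The microglia median was 1.70 (camera adjusted p = 6.12e-07, and adjusted p = 0.342 with an estimated correlation). Of 9 interferon response genes 5 rose, 0 fell and 4 did not pass (6 rose adjusted over the list alone), with Ifit2 at 1.82. The interferon call (camera adjusted p = 0.0137) ended at adjusted p = 0.0678 after quantile normalization and at adjusted p = 0.397 with an estimated correlation. Of 7 MHC class II and antigen presentation genes 4 rose and 3 did not pass (4 adjusted over the list alone, camera adjusted p = 0.0517). Of 11 oligodendrocyte precursor markers 5 rose and 6 did not pass (5 adjusted over the list alone), with the growth factor receptor gene Pdgfra at 2.71. The precursor call (camera adjusted p = 0.0227) ended at adjusted p = 0.397 with an estimated correlation. Of 11 myelinating oligodendrocyte markers 5 fell and 6 did not pass (5 adjusted over the list alone), with Ermn at -1.90 and Mag at -1.68. The myelin call (camera adjusted p = 0.0491) ended at adjusted p = 0.523 with an estimated correlation. Among 13 astrocyte and Bergmann glia markers Gfap rose by 2.41, Hopx (-1.47), Gja1 (-1.09), Gdf10 (-0.93) and S100b (-0.82) fell and 8 did not pass. Adjusted over the list alone 1 rose and 2 fell, 3 rose and 6 fell without hGFAP tumour 5, and camera gave adjusted p = 0.455.

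Of 9 stem cell markers 5 rose, among them Nes (2.04) and Cd44 (1.22), and Prom1 fell (-0.81), with the same counts adjusted over the list alone. The stem cell call (camera adjusted p = 0.044) ended at adjusted p = 0.111 after quantile normalization and at adjusted p = 0.344 with an estimated correlation. Of 12 cell cycle inhibitors and p53 targets 5 rose, 2 fell and 5 did not pass (6 and 2 adjusted over the list alone), with the p53 target gene Eda2r at 3.48 and the inhibitor gene Cdkn2c at 2.94. Their camera adjusted p of 0.0313 became adjusted p = 0.0704 without hGFAP tumour 5, adjusted p = 0.0791 after quantile normalization and adjusted p = 0.342 with an estimated correlation. Of 8 WNT pathway targets 4 rose, including Myc (3.22), and Lef1 fell (-0.55), with the same counts adjusted over the list alone. The WNT call (camera adjusted p = 0.0326) ended at adjusted p = 0.0678 after quantile normalization and at adjusted p = 0.342 with an estimated correlation. Of 11 chromatin and Polycomb genes 6 rose and 5 did not pass (7 adjusted over the list alone), with Hmgb2 at 3.33 and Hells at 2.65. The chromatin call (camera adjusted p = 0.0135) ended at adjusted p = 0.397 with an estimated correlation.

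The remaining lists did not pass camera in hGFAP tumours. In the Notch pathway 5 of 8 genes rose and 1 fell (camera adjusted p = 0.0589), and of 8 Hippo YAP targets 3 rose and 2 fell (0.631). Of 10 hypoxia and glycolysis genes 2 rose and 5 fell (0.23), and of 9 cilia genes 3 rose and 2 fell (0.926). Endothelial and pericyte markers fell in 3 of 10 cases (0.151), and of 11 fibroblast and meningeal matrix genes 2 rose, or 4 without hGFAP tumour 5, and 1 fell (0.677). Of 3 choroid plexus and ependymal markers 0 passed (0.906), and of 5 group 4 medulloblastoma markers 3 fell (0.134). Adjusted over each list alone these 8 lists had the same counts. With 2 tested genes each, 4 further lists were too small for camera. Both WNT medulloblastoma markers fell, of the group 3 markers Mab21l2 rose by 4.07, of the cerebellar territory genes En2 fell (-1.04), and both forebrain genes, Lhx2 (2.75) and Neurod6 (2.00), rose. No lymphocyte, erythrocyte or hindbrain Hox gene of the lists passed the filter on dim genes.

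**Figure D3:**
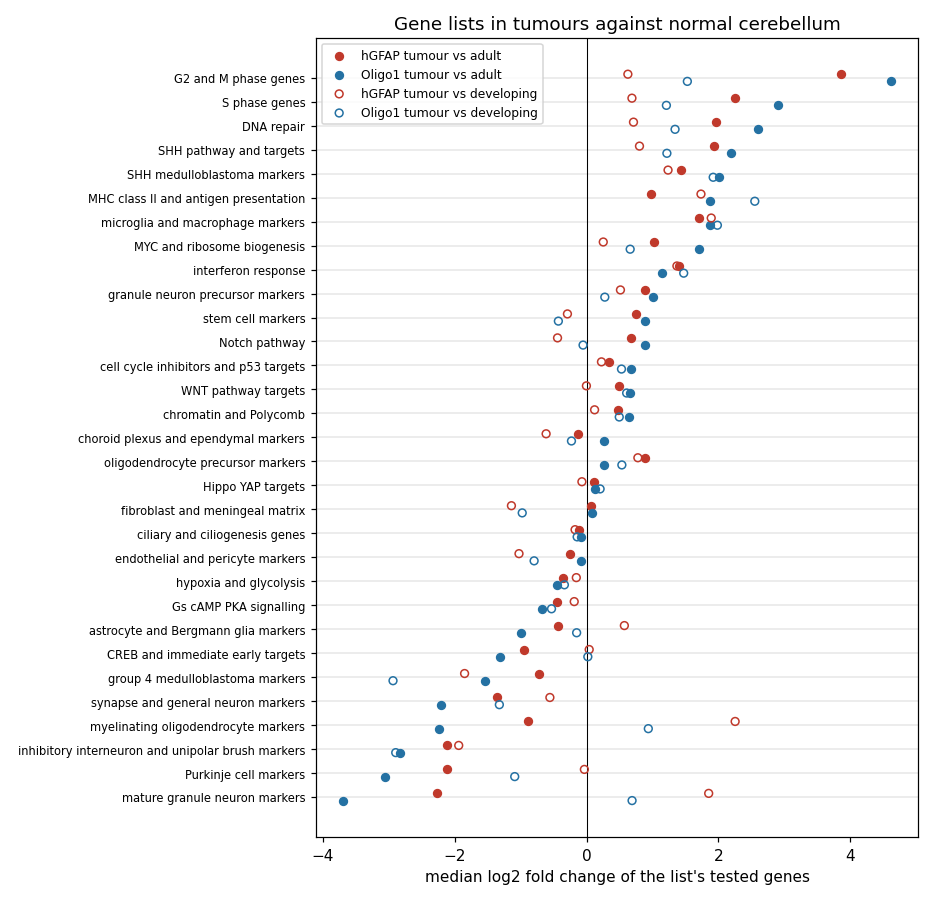
Median log2 fold change of the tested genes of each list (horizontal axis) for hGFAP and Oligo1 tumours against adult cerebellum (filled points) and against developing cerebellum (open points). Against adult cerebellum the G2 and M phase genes lay farthest right (3.86 and 4.62) and the mature granule neuron markers farthest left (-2.26 and -3.69).

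In all, limma called 5941 of 10988 genes between hGFAP tumours and adult cerebellum, 2662 higher and 3279 lower, at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1945 differed at least 2-fold. Without hGFAP tumour 5, whose values lay nearest to adult cerebellum, 7026 genes were called, and the same 18 S phase, 19 G2 and M phase, 12 microglia and 10 mature granule neuron genes kept their direction. Tumours 1 to 4 and 5 to 8 differ in the style of their array names, which could mark a batch, and 7048 and 3977 genes were called with each set of 4 alone.

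Oligo1 tumours were compared with adult cerebellum in the same way. Atoh1 rose at least 100.4-fold (log2 6.65, SE 0.60, adjusted p = 2.13e-08), to 11.63 ± 0.58 (SD, n = 8), as did Nhlh1 (6.27), Insm1 (6.27) and Mki67 (6.24). The other large rises were Top2a (6.14), Cdk6 (5.94), the mitotic kinesin gene Kif11 (5.82), the spindle checkpoint gene Bub1 (5.81), the mitotic kinase gene Cdk1 (5.78) and Nusap1 (5.75). These differences are lower bounds too, as every adult array lay below the filter value for these 10 genes. Gabra6, a GABA receptor subunit of granule neurons, fell most (log2 -5.11, SE 0.92, 34.6-fold, adjusted p = 4.06e-05), to 7.15 ± 2.17 (n = 8). Calb1, the calbindin gene of Purkinje cells (-5.01), Gsbs (-5.00), Cbln3, a cerebellin of granule neurons (-4.73), Slc17a7 (-4.42), Tmem90b (-4.41) and Grm4 (-4.38) fell as well, along with Arhgef33 (-4.61), Olfm3 (-4.43) and Dgkg (-4.33).

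Of the 13 SHH pathway genes 11 rose in Oligo1 tumours and Gli3 fell (-0.87), with the same counts adjusted over the list alone. Mycn rose by 4.00, Gli1 by 2.51 and Ptch1 by 1.13, and Boc did not pass (0.33). The SHH median was 2.20 (camera adjusted p = 3.33e-05, and adjusted p = 0.358 with an estimated correlation). All 19 G2 and M phase genes (median 4.62, camera adjusted p = 6.94e-11) and all 18 S phase genes rose (2.91, adjusted p = 1.77e-08). The 11 DNA repair genes (2.60, camera adjusted p = 7.29e-06) and the 11 MYC and ribosome biogenesis genes (1.70, adjusted p = 3.2e-05) all rose too. These counts were the same adjusted over each list alone, and each call ended at adjusted p = 0.358 with an estimated correlation. All 10 mature granule neuron markers fell (median -3.69, camera adjusted p = 0.000578), as did all 13 synapse and general neuron genes (-2.21, adjusted p = 0.00032). Of 12 Purkinje cell markers 11 fell, with Foxp2 higher by 1.06 (median -3.06, camera adjusted p = 0.000906). The counts of these 3 lists were the same adjusted over each list alone, and their calls ended at adjusted p = 0.395 with an estimated correlation. All 8 markers of inhibitory interneurons and unipolar brush cells fell (8 adjusted over the list alone), led by the glutamate decarboxylase genes Gad1 (-4.09) and Gad2 (-3.94). Their median was -2.83 (camera adjusted p = 0.00141, and adjusted p = 0.358 with an estimated correlation). Of 15 granule neuron precursor markers 8 rose, Eya1 (-1.29), Neurod1 (-0.98) and Zic2 (-0.56) fell and 4 did not pass (8 and 4 adjusted over the list alone). The precursor median was 1.01 (camera adjusted p = 0.0329, and adjusted p = 0.435 with an estimated correlation).

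Of the 24 Gs and cyclic AMP genes 15 fell, 5 rose and 4 did not pass in Oligo1 tumours (16 and 5 adjusted over the list alone), with Adcy1 at -3.58, Gnal at -3.46, Pde10a at -2.52 and Prkar2b at 1.38. The Gs median was -0.68 (camera adjusted p = 0.0152, and adjusted p = 0.358 with an estimated correlation). Of the 8 CREB targets 7 fell and Nr4a2 did not pass at -0.53 (7 adjusted over the list alone). The CREB call (camera adjusted p = 0.00694) ended at adjusted p = 0.358 with an estimated correlation. Of 11 myelinating oligodendrocyte markers 10 fell (11 adjusted over the list alone), with Ermn at -3.73 and Mag at -3.26. The myelin median was -2.23 (camera adjusted p = 0.000906, and adjusted p = 0.395 with an estimated correlation). Of 13 astrocyte markers 10 fell, with Gdf10 at -2.57, Gfap rose by 1.45 and 2 did not pass (10 and 1 adjusted over the list alone). The astrocyte call (camera adjusted p = 0.0373) ended at adjusted p = 0.0579 without hGFAP tumour 5 in the shared fit and at adjusted p = 0.428 with an estimated correlation.

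Of 12 microglia markers 10 rose in Oligo1 tumours, with C1qc at 3.16, while Mrc1 (0.45) and P2ry12 (0.20) did not pass (10 adjusted over the list alone). All 7 antigen presentation genes rose (7 adjusted over the list alone), with H2-Aa at 3.11 and Cd74 at 2.74. Both calls, of microglia (camera adjusted p = 0.000687) and antigen presentation (adjusted p = 0.0226), ended at adjusted p = 0.395 with an estimated correlation. Of 12 cell cycle inhibitors and p53 targets 10 rose, among them Eda2r (4.27), Cdkn2c (3.82) and the tumour suppressor gene Cdkn2a (2.19), and Zmat3 fell (-0.31). These counts were the same adjusted over the list alone, and the call (camera adjusted p = 0.00694) ended at adjusted p = 0.358 with an estimated correlation. Of 11 chromatin genes 8 rose and Dnmt3a fell (-0.26), also adjusted over the list alone. The chromatin call (camera adjusted p = 0.0153) ended at adjusted p = 0.395 with an estimated correlation.

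Of 9 interferon response genes 7 rose in Oligo1 tumours (camera adjusted p = 0.0815), and of 9 stem cell markers 5 rose and Prom1 fell (0.103). Of 11 oligodendrocyte precursor markers Pdgfra (2.81), Olig2 (1.71) and Cspg4 (1.26) rose while Ptprz1 (-0.89) and Nkx2-2 (-0.82) fell (camera adjusted p = 0.597). The counts of these 3 lists were the same adjusted over each list alone, and the lists did not pass camera.

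limma called 7719 of 10988 genes in Oligo1 tumours, 3931 higher and 3788 lower, of which 3228 differed at least 2-fold. With tumours 1 to 4 alone 8326 genes were called, and with tumours 5 to 8 alone 6342.

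The changes against adult cerebellum overlapped between the tumour groups. Of the genes called in both, 5579 changed in the same direction, 2535 higher and 3044 lower. Only Cdkn2d (-0.32 in hGFAP and 0.32 in Oligo1 tumours) and Gdpd3 (-1.40 and 2.02) were called in opposite directions. Independent lists of these sizes would share 2083 genes. Unchanged groups simulated against the same adult arrays shared a median of 0 and at most 105 in 50 simulations. Such groups yield few calls, so a small overlap was nearly fixed in advance. Groups changed separately that share only the adult arrays were not simulated. With the adult arrays split between the comparisons, 20 splits gave 3428 to 4326 shared genes. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.958 (simulated 0.383), with a covariance of 1.05 (simulated 0.00946).

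The comparison of the tumour groups asked whether tumours from the 2 mouse lines differ. Prm1, a protamine gene of spermatids, was higher in hGFAP tumours (log2 3.45, SE 0.38, at least 10.9-fold, adjusted p = 3.61e-05). Its 2 probe sets disagreed: one lay at 10.30 to 11.57 in hGFAP and 4.22 to 5.06 in Oligo1 tumours, the other at 7.43 to 8.21 and 6.72 to 7.39. The keratin gene Krt10 (2.83, adjusted p = 0.000163) and the Y-linked gene Uty (3.26, adjusted p = 0.0403) were higher too. The Purkinje cell genes Calb1 (2.72, SE 0.85, adjusted p = 0.0341) and Car8 (2.11) and the granule neuron genes Gabra6 (2.67, SE 0.81, adjusted p = 0.0313) and Cbln3 (2.44) were higher as well. So were Arhgef33 (2.26), Vsnl1 (2.16) and Rgs13 (2.16). The SEs come from a spread shared by all 24 arrays, and adult arrays could vary far less than tumours. The SD of Calb1 was 0.09 in adult arrays, 1.69 in hGFAP and 2.37 in Oligo1 tumours. For such genes the SE and adjusted p are likely too small. Dlx6, a homeobox gene of forebrain interneurons, was lower (-3.24, SE 0.20, at least 9.44-fold, adjusted p = 5.73e-10), at 5.73 ± 0.42 (SD, n = 8) in hGFAP tumours against 8.18 to 9.89 in the 8 Oligo1 tumours. Gdpd3 (-3.41, adjusted p = 0.000374), the germ cell gene Dazl (-3.35, adjusted p = 0.0222), H2afb3, now H2ab3 (-2.81), and the X-linked genes Xlr3b (-2.70) and Xlr4c (-1.70) were lower. Cd5l (-2.17), Slit1 (-1.83), AA388235 (-1.76) and the laminin gene Lama5 (-1.69) were lower too. For Krt10, Rgs13, Dazl, Xlr3b, Cd5l and Xlr4c every array of the lower group lay below the filter value. The differences of Krt10, Dazl and Cd5l are lower bounds in size in the sense given above. In the lower group Rgs13 ranged from 3.54 to 7.08, Xlr3b from 3.34 to 7.39 and Xlr4c from 5.09 to 7.34. Such ranges show no floor, so no bound is claimed for these genes.

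Of 11 myelinating oligodendrocyte markers 8 were higher in hGFAP than in Oligo1 tumours (10 adjusted over the list alone), with Ermn at 1.83 and Mog at 1.65. Of 13 astrocyte markers 7 were higher (8 adjusted over the list alone), with Gdf10 at 1.63. Both calls, of myelin (median 1.29, camera adjusted p = 8.42e-06) and astrocyte markers (0.74, adjusted p = 0.000257), ended at adjusted p = 0.59 with an estimated correlation. The myelin count was 5 without hGFAP tumour 5 (median 1.25, camera adjusted p = 3.01e-05). Of 10 mature granule neuron markers 4 were higher (9 adjusted over the list alone, median 1.40, camera adjusted p = 0.000371). Of 12 Purkinje cell markers 4 were higher (8 adjusted over the list alone, median 1.01, camera adjusted p = 0.000257), and of 13 synapse and general neuron genes 4 (11 adjusted over the list alone, median 0.87, adjusted p = 0.000135). These 3 neuron calls ended at adjusted p = 0.638 with an estimated correlation. Without hGFAP tumour 5, 0 granule neuron (median 1.16, camera adjusted p = 0.00208), 1 Purkinje (0.84, adjusted p = 0.00107) and 1 synapse gene (0.69, adjusted p = 0.000696) were higher. Of 24 Gs and cyclic AMP genes 9 were higher, with Adcy1 at 1.62 and Gnal at 1.30, and Pde1c was lower at -1.02 (9 and 2 adjusted over the list alone). The Gs call (camera adjusted p = 0.00699) ended at adjusted p = 0.59 with an estimated correlation. The Gs counts were 3 higher and 0 lower without hGFAP tumour 5 (camera adjusted p = 0.0194).

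Of 8 inhibitory neuron markers Gad1 was higher by 1.73 in hGFAP tumours (0 adjusted over the list alone), and of 11 oligodendrocyte precursor markers Nkx2-2 (0.90), Olig1 (0.86) and Ptprz1 (0.56) were higher (5 adjusted over the list alone). Both lists had camera adjusted p = 0.0177, and adjusted p = 0.638 with an estimated correlation. The inhibitory neuron call also ended without hGFAP tumour 5 (adjusted p = 0.064) and after quantile normalization (adjusted p = 0.192). By fry the inhibitory (adjusted p = 0.0829), oligodendrocyte precursor (0.104) and mature granule neuron lists (0.0543) did not pass.

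Of 19 G2 and M phase genes Birc5 (-0.88) and Bub1b (-0.85) were lower in hGFAP than in Oligo1 tumours (1 adjusted over the list alone, median -0.86, camera adjusted p = 0.000371). Of 18 S phase genes Slbp (-0.55) was lower (1 adjusted over the list alone, median -0.66, camera adjusted p = 0.000745). The medians without hGFAP tumour 5 were -0.44 for G2 and M phase genes (1 lower, camera adjusted p = 8.24e-05) and -0.37 for S phase genes (adjusted p = 0.000696). Both calls ended at adjusted p = 0.664 with an estimated correlation, and fry gave adjusted p = 0.104 and 0.0937. Of 11 DNA repair genes 4 were lower (8 adjusted over the list alone), with Fancd2 at -1.22, and of 11 MYC and ribosome biogenesis genes 3 (7 adjusted over the list alone), with Ddx21 at -0.66. Both calls (camera adjusted p = 0.00114 and 0.000981) ended at adjusted p = 0.638 with an estimated correlation, and at adjusted p = 0.0617 and 0.0543 by fry. Only 2 DNA repair genes were lower without hGFAP tumour 5, and the medians moved from -0.64 to -0.40 for DNA repair and from -0.50 to -0.31 for MYC genes. Of 12 cell cycle inhibitors and p53 targets Cdkn2a (-1.42), Cdkn2d (-0.65) and Trp53inp1 (-0.50) were lower (6 adjusted over the list alone). Their call (camera adjusted p = 0.00235) ended at adjusted p = 0.59 with an estimated correlation. Of 7 antigen presentation genes H2-Aa (-1.51) and H2-Eb1 (-1.43) were lower (3 adjusted over the list alone). Oligo1 tumours 3 and 4 held the highest H2-Aa levels (10.58 and 11.02, the other 6 Oligo1 tumours 7.89 to 8.62). That call (camera adjusted p = 0.0439) ended at adjusted p = 0.0521 without hGFAP tumour 5, at 0.0937 by fry and at adjusted p = 0.664 with an estimated correlation. Of 13 SHH pathway genes Smo (-0.61) and Ptch1 (-0.29) were lower (2 adjusted over the list alone, camera adjusted p = 0.0581, and adjusted p = 0.0418 with arrays centred on their medians). The SHH median moved from -0.45 to -0.11 without hGFAP tumour 5 (adjusted p = 0.174). Of 12 microglia markers Mrc1 was higher by 0.80 (1 adjusted over the list alone, median -0.17, camera adjusted p = 0.617). Without hGFAP tumour 5, 4 were higher (median 0.06, camera adjusted p = 0.0201).

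limma called 2091 of 10988 genes between the tumour groups, 1146 higher and 945 lower in hGFAP, of which 265 differed at least 2-fold, 226 higher and 39 lower. The count was 223 in a fit of only these groups, 4315 with array weights, 1884 among tumours 1 to 4, 7 among tumours 5 to 8 and 2856 with the naming style as a block, and leaving out single tumours moved it from 507 (without Oligo1 tumour 1) to 3175 (without hGFAP tumour 7). By Xist and Uty 7 of 8 hGFAP but 2 of 8 Oligo1 tumours were male, and 28 genes were called with sex as a covariate, while the 2091 genes kept a median share of 0.803 of their log2 fold change, all with the same sign. After quantile normalization 956 were higher and 1286 lower. Dlx6 passed under every setting tried (adjusted p at most 0.00958), Prm1, Krt10 and Gdpd3 under all but tumours 5 to 8 alone (adjusted p = 0.0726, 0.0903 and 0.142, and 0.546 for Krt10 and Gdpd3 in a fit of these 2 groups). With the brightest probe set Prm1 differed by 0.55. Calb1, Gabra6, Cbln3, Arhgef33, Vsnl1, Car8, Uty and AA388235 each failed without any 1 of hGFAP tumours 3, 5 or 6 or Oligo1 tumours 1, 2 or 3, and some without other tumours, with leave-one-out adjusted p up to 0.0936 (Arhgef33 without hGFAP tumour 3). Over all 37 settings tried, differences went down to 0.15 for Arhgef33, 0.29 for Cbln3, 0.33 for Car8, 0.42 for Gabra6 and 0.48 for Calb1. Their limma adjusted p went up to 0.938, 0.918, 0.864, 0.863 and 0.857. H2afb3 failed without any 1 of 10 tumours, at most at 0.0837 (without hGFAP tumour 3), and Dazl without Oligo1 tumour 1 (0.0526). Over all settings Dazl lost the call in 11 of 37, with a difference as small as -1.50 and limma adjusted p up to 0.546. H2afb3 lost it in 18 of 37, Lama5 in 6 of 37 and Cd5l in 4 of 36.

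Against developing cerebellum, hGFAP tumours were compared with tissue of embryonic days 15 and 18 and postnatal day 0. Later ages of development were not sampled. Lcn2 rose at least 102-fold (log2 6.67, SE 0.49, adjusted p = 1.3e-09), Gpnmb by 5.88, the acute phase gene Serpina3n by 5.29, Gabra6 by 4.94 (SE 1.09, adjusted p = 0.00146) and the astrocyte filament gene Gfap by 4.88. All but Gfap lay below the filter value in every developing array, so their differences are lower bounds. The transthyretin gene Ttr, a choroid plexus marker, fell (-5.05, SE 1.82, adjusted p = 0.0407), as did the cadherin gene Cdh9 (-4.84), Sostdc1 (-4.70) and H2afb3 (-4.46). St8sia2, a polysialyltransferase of the developing brain, fell as well (-4.34, SE 0.21, adjusted p = 6.12e-13). For Cdh9, Sostdc1 and St8sia2 every hGFAP array lay below the filter value, so these falls are lower bounds in size. In Oligo1 tumours Gpnmb (5.98), Lcn2 (5.96), the lysozyme gene Lyz2 (5.16), Serpina3n (4.94) and H2-Aa (4.75) rose, all from levels below the filter value in every developing array. Cdh9 (-5.21), the neurofilament gene Nefl (-4.90), St8sia2 (-4.73), the imprinted RNA H19 (-4.69) and the homeobox gene Meis2 (-4.67) fell without overlap, those of Cdh9 and St8sia2 again as lower bounds in size. With strain as a covariate the hGFAP calls of Gabra6 (adjusted p = 0.136), Ttr (0.565), Sostdc1 (0.054) and H2afb3 (0.134) and the Oligo1 call of Nefl (0.0674) ended. The Ttr call also ended without any 1 of the developing arrays or of hGFAP tumours 1, 3, 6, 7 and 8, with adjusted p from 0.0509 to 0.116.

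Of 13 SHH genes 4 rose in hGFAP tumours against developing cerebellum, Sfrp1 (2.11), Ptch1 (1.35), Gli1 (1.33) and Hhip (1.24), Gli3 fell (-2.09) and 8 did not pass, or 6 and 1 adjusted over the list alone. Without hGFAP tumour 5, 11 rose and 1 fell (median 1.11, camera adjusted p = 0.00105). In Oligo1 tumours 9 rose, with Atoh1 at 2.30 and Gli1 at 1.90, and Gli3 fell (-2.22), or 11 and 1 adjusted over the list alone. The SHH medians were 0.80 (camera adjusted p = 0.0202, and adjusted p = 0.574 with an estimated correlation) and 1.22 (adjusted p = 0.0062, and adjusted p = 0.633 with an estimated correlation). Of 18 S phase genes Pcna (1.09), E2f2 (0.74) and Ung (0.69) rose in hGFAP tumours (0 adjusted over the list alone), and 15 without hGFAP tumour 5 (median 0.86, camera adjusted p = 9.33e-05). This call (camera adjusted p = 0.0437) ended at adjusted p = 0.218 by fry and at adjusted p = 0.747 with an estimated correlation. Of 19 G2 and M phase genes 0 passed (0 adjusted over the list alone, median 0.63, camera adjusted p = 0.171). Without hGFAP tumour 5, 18 rose (median 1.03, camera adjusted p = 4.55e-05). In Oligo1 tumours 15 S phase genes (15 adjusted over the list alone, median 1.21) and 10 G2 and M phase genes rose (16 adjusted over the list alone, 19 without hGFAP tumour 5 in the shared fit, median 1.53). Their calls (camera adjusted p = 0.00116 and 0.00363) ended at adjusted p = 0.692 and 0.758 with an estimated correlation. Of 11 DNA repair genes 10 rose in Oligo1 tumours (11 adjusted over the list alone), with Fancd2 at 2.39 (camera adjusted p = 0.00118, and adjusted p = 0.633 with an estimated correlation). In hGFAP tumours 1 rose (1 adjusted over the list alone, camera adjusted p = 0.0349, and adjusted p = 0.686 with an estimated correlation), or 11 without hGFAP tumour 5. This hGFAP call ended in 2 of 6 settings, the estimated correlation included.

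Of 24 Gs and cyclic AMP genes 6 were lower than in developing cerebellum in hGFAP tumours (5 adjusted over the list alone) and 13 in Oligo1 tumours (14 adjusted over the list alone). Gnal stood at -1.74 and -3.05, Prkar2b at -1.77 and -1.55 and Gpr161 at -1.22 and -0.85. The Gs calls (camera adjusted p = 0.0126 and 0.000496) ended at adjusted p = 0.336 and 0.323 with an estimated correlation. The CREB list did not pass there, with 2 of 8 genes lower in each group (2 adjusted over the list alone), medians of 0.04 and 0.02 and camera adjusted p of 0.467 and 0.326.

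Markers of inhibitory neurons and unipolar brush cells were lower than in developing cerebellum, 4 of 8 in hGFAP (5 adjusted over the list alone) and 8 of 8 in Oligo1 tumours (8 adjusted over the list alone). Tcfap2b stood at -3.08 and -4.04 and the interneuron precursor gene Pax2 at -2.76 and -3.13. Their medians were -1.94 (camera adjusted p = 5.9e-05, and adjusted p = 0.336 with an estimated correlation) and -2.89 (adjusted p = 4.88e-05, and adjusted p = 0.323 with an estimated correlation). Endothelial and pericyte markers fell in 8 of 10 cases in hGFAP (8 adjusted over the list alone) and in 7 of 10 in Oligo1 tumours (8 adjusted over the list alone), with the growth factor receptor gene Kdr at -2.34 and -1.99. The endothelial calls (camera adjusted p = 2.04e-06 and 0.000496) ended at adjusted p = 0.336 and 0.447 with an estimated correlation. Fibroblast and meningeal matrix genes fell in 7 of 11 cases in each group (7 adjusted over the list alone in each), while Pdgfra rose by 1.21 in Oligo1 tumours. The fibroblast calls (camera adjusted p = 0.000864 and 0.00118) ended at adjusted p = 0.336 and 0.323 with an estimated correlation.

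Microglia markers were higher than in developing cerebellum in 11 of 12 cases in hGFAP and in 10 of 12 in Oligo1 tumours (11 adjusted over the list alone in each), with C1qc at 2.95 and 3.26. The microglia calls (camera adjusted p = 5.88e-07 and 0.000297) ended at adjusted p = 0.345 and 0.538 with an estimated correlation. Antigen presentation genes rose in 5 of 7 and 7 of 7 cases (6 and 7 adjusted over the list alone), with Cd74 at 3.45 and 4.53. These calls (camera adjusted p = 0.00161 and 0.000696) ended at adjusted p = 0.428 and 0.447 with an estimated correlation. Myelinating oligodendrocyte markers rose in 9 of 11 cases in hGFAP tumours (9 adjusted over the list alone), led by Mobp at 3.35, and mature granule neuron markers in 5 of 10 (6 adjusted over the list alone). The myelin call (camera adjusted p = 4.49e-05) ended at adjusted p = 0.407 with an estimated correlation. The granule neuron call (camera adjusted p = 0.0126) ended at adjusted p = 0.0746 without hGFAP tumour 5 and at adjusted p = 0.574 with an estimated correlation.

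limma called 3101 genes between hGFAP tumours and developing cerebellum, 1637 higher and 1464 lower, and 5212 between Oligo1 tumours and developing cerebellum, 3020 higher and 2192 lower. With strain as a covariate, estimated from the adult arrays, the counts were 779 and 1454, and without the array of embryonic day 15 the hGFAP count was 1954. The C57BL/6 adult arrays were of postnatal days 95 and 122 and female by Xist and Uty. Those of mixed strain were of day 60 or recorded only as adult, and 2 were male. The strain covariate therefore also holds age and sex. Array weights raised both counts, as given below.

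Over the genes tested, hGFAP tumours correlated with adult cerebellum at a mean r of 0.730 ± 0.123 (SD, n = 8) and with the postnatal day 0 array at 0.812 ± 0.033. Oligo1 tumours correlated with adult cerebellum at 0.583 ± 0.096 (n = 8) and with postnatal day 0 at 0.759 ± 0.047. The mean difference between the 2 correlations was 0.0824 ± 0.127 in hGFAP tumours, smaller than the spread between tumours, but 0.118 ± 0.0849 (n = 7) without hGFAP tumour 5. In Oligo1 tumours it was 0.176, with 0.0433 without a filter and 0.394 over the genes most variable among normal arrays. No test was made, since each age had 1 array. These correlations are across genes, which are not independent replicates. hGFAP tumour 5 had the highest correlation with adult cerebellum (0.927), against at most 0.846 in the other hGFAP tumours.

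**Figure D4:**
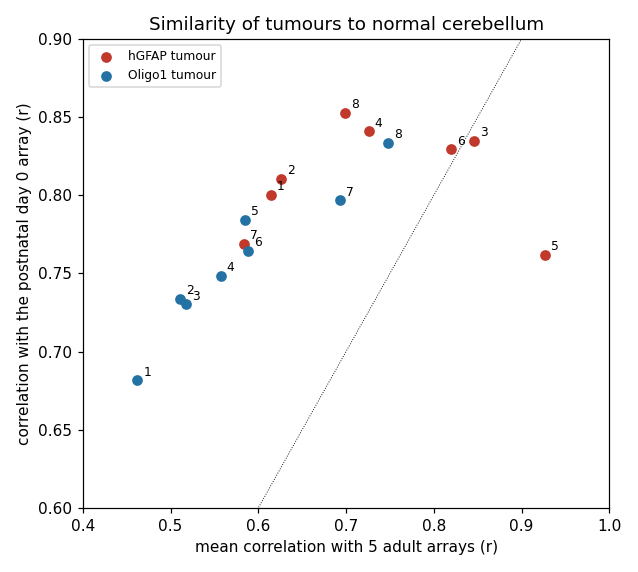
Correlation of each tumour with the postnatal day 0 array (vertical axis) against its mean correlation with the 5 adult arrays (horizontal axis), across genes, with tumours numbered by replicate and a dotted line of equality. hGFAP tumour 5 lies at 0.927 with adult cerebellum and 0.762 with postnatal day 0, below the line.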

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

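The tests of a poor array, of Gnas in hGFAP tumour 5, of arrays centred on their medians, of sex, over all called genes and over those that pass with it, and of both explanations for Prm1 were chosen only after the result was seen. A sample stood apart in 19 of 134 groups of values, where chance gives about 1 in 20 groups at the Dixon critical values used, and the groups share arrays. Most of these 19 were values of hGFAP tumour 5. It was lowest among hGFAP tumours for Atoh1 at 6.62 (others 10.59 to 12.18), Insm1 at 8.42, Nhlh1 at 7.44, Mki67 at 6.87, Top2a at 6.12, Ccna2 at 7.91, Cdk6 at 7.36, Hsd11b2 at 7.38, Gpnmb at 8.25 and Lcn2 at 10.01. It was highest for Cdh9 at 6.49, and its median over all probe sets was 7.37, against 7.62 to 7.67 in the other 7.

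hGFAP tumour 5 lay nearer to adult cerebellum than the other 7 hGFAP tumours, and a poor array may remain: its 7899 genes above the filter value were fewest (at least 8769 in the other 23), while its highest correlation with any array was 0.929 (the lowest of the others 0.905), and a first test against adult arrays only (0.927, at most 0.846 in other hGFAP tumours) restated the pattern and was dropped. For tissue like the 5 adult arrays, 16 of 23 bright Gnas probe sets lay below all of them with arrays centred (21 as deposited). An adult array against the other 4 had at most 10 and 7. These probe sets measure 1 gene in 1 array, and bright probe sets of other genes were not counted. The test thus cannot decide whether hGFAP tumour 5 is normal tissue, cerebellum beside a tumour included. As normal cerebellum it would have few of the genes higher in Oligo1 tumours above all adult arrays, and the share was 26.5% as deposited (adult arrays against each other 15.1% to 31.0%), which met a bound of at most 30% set in advance for normal tissue, a bound set aside after the result was seen because the low array median lowers the share, and 49.6% with arrays centred (16.6% to 25.9%), which assumes the offset to be technical. As a tumour mixed with normal cerebellum it should give 1 tumour share from risen and fallen genes, and the shares differed by -0.332 as deposited (at most 0.152 in the others), a bound set in advance as evidence against mixing but set aside here because the low array median pulls both shares apart; with arrays centred they differed by 0.0695 (0.105 at most in the others), but both shares lay near 0 (0.0779 and 0.00839), where a small difference is nearly forced, so this says little on mixing and a mixed sample or a less proliferative tumour may remain.

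The difference between hGFAP and Oligo1 tumours may reflect more normal cerebellum in the hGFAP samples, as 98.7% of the 832 called genes at least 2-fold from adult (821) differed towards adult cerebellum. More differentiated tumour cells would give the same direction and were not tested, and 8.61% of the called genes lay outside the range from Oligo1 tumours to adult. Sex could account for part, since 7 of 8 hGFAP but 2 of 8 Oligo1 tumours were male by Xist and Uty. With sex as a covariate the called genes kept a median share of 0.803 of their log2 fold change (median size 0.55 before and 0.45 after, median SE 0.16 and 0.18), and most calls ended as the fold fell and the SE rose. The 28 genes that pass with sex as a covariate kept at least 0.856 of theirs, Dlx6 at -3.24 before and -3.18 after. Their choice by that fit nearly forces a large share, so the share is no evidence. Their limma adjusted p under 0.05 in that fit argues against sex as their whole cause. That holds only if sex acts alike in all 4 groups, as the fit assumes. Within the tumours only 1 female hGFAP and 2 male Oligo1 tumours part sex from line. For the other called genes sex and line cannot be told apart.

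Prm1 was high in all 8 hGFAP and low in all 8 Oligo1 tumours. Testis RNA or activity of spermatid genes would raise Prm2, Prm3, Tnp1 and Tnp2, whose median log2 difference was 0.0345 and whose highest was 0.09, against 3.45 for Prm1. Whether a Cre transgene carries protamine sequence stays open: the gap of 2.80 between the lowest hGFAP and the highest Oligo1 tumour restates the pattern and supports nothing. The difference rested mostly on 1 of the 2 Prm1 probe sets. It lay at 10.30 to 11.57 in hGFAP and 4.22 to 5.06 in Oligo1 tumours. Adult array 3 held the hGFAP pattern, at 11.74 for that probe set and 7.52 for the other (hGFAP tumours 7.43 to 8.21). Its gene level was 9.63, within the hGFAP range, where the transgene explanation expected every normal array below it. The labels used here do not describe the transgenes.

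Splits of the same arrays into groups of the same sizes, 100 drawn per comparison, were counted with the real one included. Only the real split called as many genes for hGFAP (5941, highest other 1148) and Oligo1 tumours (7719, highest other 5867) against adult. The same held for Oligo1 tumours against developing cerebellum (5212, highest other 765). That is 1 in 100, the smallest share that 100 splits can show, so over 5 comparisons chance is not excluded by it. For hGFAP tumours against developing cerebellum 2 splits (3101, highest other 3117) and for hGFAP against Oligo1 tumours 4 splits (2091, highest other 4296) called as many. Both are under the 5 in 100 set in advance, but with 100 splits in each of 5 comparisons chance is not excluded for these 2 either. The split with 3117 genes parted hGFAP tumours 3, 5 and 6 from the other arrays. The split with 4296 genes set hGFAP tumours 3, 4, 5, 6 and 8 and Oligo1 tumours 4, 7 and 8 against the rest, which points to a structure of the samples other than the line.

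Uty was lowest in hGFAP tumour 7 at 4.13 (others 8.59 to 9.18). Oligo1 tumour 6 was highest in its group for Cdh9 at 5.52 and Meis2 at 8.12 (others 5.16 to 5.67), and Oligo1 tumour 8 was lowest for Cdk6 at 11.08. Among adult arrays, array 2 was lowest for Top2a at 4.59 and Cbln3 at 12.55, and array 5 was highest for Eomes at 9.38. Of 30 genes tested, 7 differed between the tumour groups in their change against adult cerebellum, which with shared adult arrays is the contrast of hGFAP with Oligo1 tumours and restates its calls: Calb1 by 2.72 (limma adjusted p = 0.0341), Gabra6 by 2.67 (0.0313), Cbln3 by 2.44 (0.0359), Arhgef33 by 2.26 (0.0439), Olfm3 by 1.88 (0.0292), Tmem90b by 1.85 (0.0216) and Slc17a7 by 1.78 (0.0403).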

How the results depend on the processing

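Sex and granule marker covariates and fits without hGFAP tumour 5 or without it and Oligo1 tumour 6 were chosen only after seeing the data, as were fits of only the tumour groups with a block, a covariate or 1 naming style. Among Gnas, the other named genes and the lists no called result reversed its direction, and other called genes were not checked for this. Medians of 13 lists that camera did not call changed sign. Of the named genes' alternatives 2100 kept the call and 234 lost it. Of those of called lists 387 kept the call and 117 lost it, 84 of them with an estimated correlation. A 2-fold minimum left 1945 and 3228 genes in hGFAP and Oligo1 tumours against adult, 265 between the tumour groups and 1168 and 1939 against developing cerebellum, by construction. The stricter filter tested fewer genes and left 5082 (Oligo1 against adult), 1935 and 3282 (hGFAP and Oligo1 against developing). Between the tumour groups the 2091 calls became 1262 with the brightest probe set, 223 in a fit of only these groups, 4315 with array weights, 1884 in tumours 1 to 4, 7 in tumours 5 to 8, 36 with the granule covariate, 28 with the sex covariate and 1375 without hGFAP tumour 5 and Oligo1 tumour 6. Leaving out 1 tumour gave 507 (Oligo1 1) to 3175 (hGFAP 7), with 535, 1158 and 589 without hGFAP 3, 5 and 6 and 1001 and 723 without Oligo1 2 and 3. Quantile normalization moved the higher share from 54.8% to 42.6%. With a replicate block 3155 genes were called, but of 8 same-number pairs 3 correlated over 0.1 (-0.495 to 0.591) and 1 hGFAP tumour was closest to its own number, so the numbers mark no shared origin. In fits of only the tumour groups 173 were called with the replicate block, 882 with the naming style block, 201 in tumours 1 to 4, 2 in tumours 5 to 8 and 11 with the granule covariate. Against developing cerebellum array weights gave 6755 (hGFAP) and 7892 (Oligo1) genes and strain 779 and 1454. The hGFAP count was 1954 without embryonic day 15, 4487 without hGFAP tumour 5 (the leave-one-out range) and 4925 without it and Oligo1 tumour 6. The Gnas difference of hGFAP tumours from developing cerebellum was -1.79 with strain (adjusted p = 0.0763). The Oligo1 difference in correlation moved from 0.176 to 0.0433 without a filter and 0.394 over the genes most variable among normal arrays. Except where fewer genes are named, the cause was not tested. Dim genes limit the values: those under the filter were not tested.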

Other observations

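The genes in this part, and which of the lists it describes, were chosen after their values were seen. Dlx6 lay at 8.18 to 9.89 in the 8 Oligo1 tumours and lower in every other array, and its neighbour Dlx5, a homeobox gene of the same pair, was lower in hGFAP than in Oligo1 tumours by limma (-1.30, adjusted p = 6.57e-05). Krt10 lay at 7.77 to 9.90 in hGFAP tumours other than tumour 5 (6.17) and at 5.24 to 6.53 in Oligo1 tumours. Dazl, a germ cell gene, lay at 11.98, 9.31, 11.30 and 11.00 in Oligo1 tumours 1, 2, 3 and 7, at 6.55 in tumour 6 and at 4.54 to 4.87 in the other Oligo1 tumours. Gdpd3 lay at 10.03 to 10.70 in Oligo1 tumours and at 5.86 to 6.67 in hGFAP tumours other than 5 (8.72) and 7 (9.69). Ttr ranged from 5.52 to 13.23 among adult arrays. Among genes whose hGFAP mean lay outside the range from Oligo1 tumours to adult cerebellum were the phospholipase gene Pla2g5 (1.43 higher in hGFAP than in Oligo1 tumours, adjusted p = 0.00648), Enpp6 (1.35), Ifi203 (1.34), the heat shock gene Hspb8 (1.05) and Amigo2 (1.04).

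Against developing cerebellum, 4 of 9 interferon response genes rose in hGFAP tumours (8 adjusted over the list alone, and 8 without hGFAP tumour 5) and 5 in Oligo1 tumours (5 adjusted over the list alone). These calls (camera adjusted p = 0.00842 and 0.0343) ended at adjusted p = 0.574 and 0.693 with an estimated correlation. Of 5 group 4 medulloblastoma markers 3 fell in each tumour group, also adjusted over the list alone (camera adjusted p = 0.0368 and 0.0222, and adjusted p = 0.336 and 0.323 with an estimated correlation), and 1 rose in hGFAP tumours. Of 13 synapse and general neuron genes 7 fell in Oligo1 tumours (8 adjusted over the list alone, camera adjusted p = 0.00116, and adjusted p = 0.633 with an estimated correlation) and 3 in hGFAP tumours (6 without hGFAP tumour 5, camera adjusted p = 0.115). Of 12 cell cycle inhibitors and p53 targets 9 rose and 1 fell in Oligo1 tumours, also adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.447 with an estimated correlation), and 5 rose and 1 fell in hGFAP tumours (camera adjusted p = 0.142). Of 11 MYC and ribosome biogenesis genes 7 rose in Oligo1 tumours, also adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.692 with an estimated correlation), and 2 in hGFAP tumours (5 without hGFAP tumour 5, camera adjusted p = 0.279). Of 13 astrocyte markers 4 rose and 1 fell in hGFAP tumours (5 and 1 adjusted over the list alone). That call (camera adjusted p = 0.0456) ended in 4 of 6 settings, among them at adjusted p = 0.184 without hGFAP tumour 5 and at adjusted p = 0.591 with an estimated correlation. In Oligo1 tumours 3 astrocyte markers rose and 3 fell (camera adjusted p = 0.993). In hGFAP tumours 3 of 11 oligodendrocyte precursor markers rose (camera adjusted p = 0.0349, and adjusted p = 0.574 with an estimated correlation), and of 8 Notch genes 1 rose and 4 fell (camera adjusted p = 0.0429, 0.0831 without hGFAP tumour 5, and adjusted p = 0.428 with an estimated correlation). Across all arrays the first principal component held 62.0% of the variance and the next 14.1%.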
